A study of Drosophila melanogaster with 3 samples.

How the data were processed

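RNA of whole pupae was measured on 3 two-colour oligonucleotide arrays. Per the labels, flies were kept at 25 °C, 1 µg of total RNA was reverse transcribed for 2 h and amplified by in vitro transcription for 14 h, and the cRNA was coupled to dyes, with wild type in Cy3 and the dcr-2 mutant in Cy5 on every array. The series design text states 3 biological replicates per genotype. All 3 arrays sat on 1 slide in the file headers, so a slide effect could not be tested.

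The spot intensity values (mean signal and median local background per channel) are unprocessed, per the file headers, and come from Agilent Feature Extraction 9.5.1.1 on array design 018972. The processed signals in the same files are intensity values after background subtraction with spatial detrending and LOWESS dye normalization, per the file headers. The log10 ratios of Cy5 over Cy3 in the files derive from those processed signals, per the file headers. The deposited value table of the series holds log10 ratios, since each column differed from the scanner's ratio by less than 0.005 in 45020 rows. Scale and direction are known from that match and the channel labels. The columns of the value table have a median of 0, and between 10.2% and 11.0% of its values are exactly 0.

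Ratios were computed with R 4.3.3 and limma 3.58.1. Signals were background-corrected with normexp (offset 50) and normalized by loess within each array, with control spots at weight 0. Spots marked as non-uniform or population outliers were left out (110, 173 and 320 gene spots on the 3 arrays), and spots of 1 probe were averaged. A probe entered if it was well above background in the same channel on all 3 arrays and was measured on at least 2. The brightest probe represented a gene. Several probes passed for 4703 genes, and in 570 of these the probes' ratios spanned 1 or more on the log2 scale. The median of all genes moved by less than 0.1 under each setting.

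Of 32162 probes, 20773 were matched to a gene of a RefSeq table of the Release 6 assembly, used for names only (18121 by locus tag, 713 by transcript, 1179 by symbol and 760 by synonym). A further 584 kept the name in the file, and 10805 had none and entered no gene count. Probe coordinates are those of the files (dm3). No genome or probe sequence was used here.

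The test was an intercept fit in limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05), with a log2 ratio of at least 1 for a 2-fold difference. Precision is limited by the number of arrays, 3. In simulated data on the 12767 genes of this comparison, 2% of genes changed by 1 on the log2 scale were recovered, 60% of those changed by 2, 96% by 4 and 100% by 6, with 7 false calls. At each size 50 genes were changed, so the simulation made many more calls than the real data. Its false calls cannot be set against the real count. Before the data were examined, 45 gene lists were fixed. The 44 with at least 5 tested members were tested with camera (inter-gene correlation 0.01), with an estimated correlation and fry beside it. The list of transposons had fewer and was not tested. A simulated shift of 0.5 in 1 list was found with an adjusted p of 3.28e-08 by camera, with 0 other lists called. In both simulations the genes were drawn independently. In the real data the estimated correlation was 0.47 for cytoplasmic ribosomal protein genes and 0.89 for oxidative phosphorylation genes. The simulations therefore do not measure false calls among correlated genes. After the members were matched to the table, 4 members that had matched a wrong gene through a synonym or a name prefix were removed. Single-channel values were taken after loess and Aquantile normalization, and lower bounds were computed from these.

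Named genes were fixed by rule: the 6 highest and 6 lowest among genes passing both thresholds with 1 direction on all arrays, the 8 highest and 8 lowest of these with names, Dcr-2, r2d2, AGO2, loqs, mus308 and Vago, and up to 4 members with the smallest p of each list described. A member of 1 list that this rule takes is not reported here. The 18 lists described were chosen after their values were seen. Alternatives covered background correction, normalization, the filter, flagged spots, probes per gene, the test, the value table and leaving out each replicate. Correction for probe base composition was not run.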

Results

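Gene expression was compared between whole pupae of wild-type Drosophila melanogaster and pupae mutant for dcr-2, which encodes Dicer-2, the enzyme that cuts long double-stranded RNA into small interfering RNAs (siRNAs). The mutant pupae (y w eyFLP) carried a frameshift allele (L811fsX) over a stop allele (R416X), each on an FRT42D chromosome. The wild type also carried an FRT42D chromosome and the eyFLP transgene, without these alleles. Each of 3 arrays held 1 wild-type RNA labelled with Cy3 and 1 mutant RNA labelled with Cy5, giving 3 biological replicates per genotype and 6 RNAs. No array had the dyes the other way round, so a difference between genotypes and a difference between dyes cannot be told apart on these arrays. All ratios are log2 of mutant over wild type.

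A small set of genes differed strongly and steadily between dcr-2 mutant and wild-type pupae. Of 12767 genes tested, 16 passed an adjusted p of 0.05 by limma, 10 higher and 6 lower in the mutant, and all 16 differed at least 2-fold with the same direction on 3 of 3 arrays. Su(P) (CG4086, probe at 3L 16603818 to 16603877) was higher by 6.77 ± 0.28 (SD, n = 3, adjusted p = 0.00475). Tengl4 (CG4683, 3R 6777374 to 6777433), a testis endonuclease G-like gene, was higher by 6.48 ± 0.35, and its other probe gave 6.54 ± 0.33. Their order depended on the background correction, as the scanner's processed signals gave 7.64 for Su(P) and 7.93 for Tengl4. CG3927 on 2R was higher by 5.64 ± 0.91 (7.28 with the processed signals), with its wild-type signal well above background on 2 of 3 arrays. CG17560 on 3R was higher by 4.83 ± 0.26. The other 3 higher genes measured in both channels were CG3857 (4.004 ± 0.08), CG1309 (4.002 ± 0.16) and CG7542 (3.29 ± 0.38). A further probe of CG3857 gave a smaller and less steady 2.73 ± 0.67.

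In the wild type, 3 of the higher genes were not well above background on any array, so only a lower bound can be given for them. CG9308 on 2R was at least 66.7-fold higher in the mutant (adjusted p = 0.0206), mthl8 at least 32.6-fold higher (adjusted p = 0.00475) and Ugt35B1 at least 22.9-fold higher (adjusted p = 0.00823). mthl8 belongs to the methuselah-like family of G protein-coupled receptors and Ugt35B1 is a UDP-glycosyltransferase. A further probe of CG9308 did not share the size of the difference, at 0.50 ± 0.25 on the 2 arrays that measured it. These bounds set the mean of the bright channel against the higher of the dim probe's own signal and the lowest signal well above background, and they are open to dye bias.

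Among the lower genes, CG12003 on 3L (1567743 to 1567802) changed most, at -6.37 ± 0.40 (SD, n = 3, adjusted p = 0.00475). The ratio of CG17177 on 3L was -4.36 ± 0.18, of CG33259 on 3L -3.002 ± 0.15, of CG14693 on 3R -2.99 ± 0.35 and of CG13358 on X -2.43 ± 0.08. The mutant signal of CG33259 was well above background on 1 of 3 arrays, so the size of its difference is not fixed, and the processed signals gave -4.94. Pp1-Y1, a Y-linked protein phosphatase 1 gene, was not well above background in the mutant on any array and was at least 6.86-fold lower there (adjusted p = 0.0378). Of the 16 genes, 13 rested on 1 probe.

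**Figure D1:**
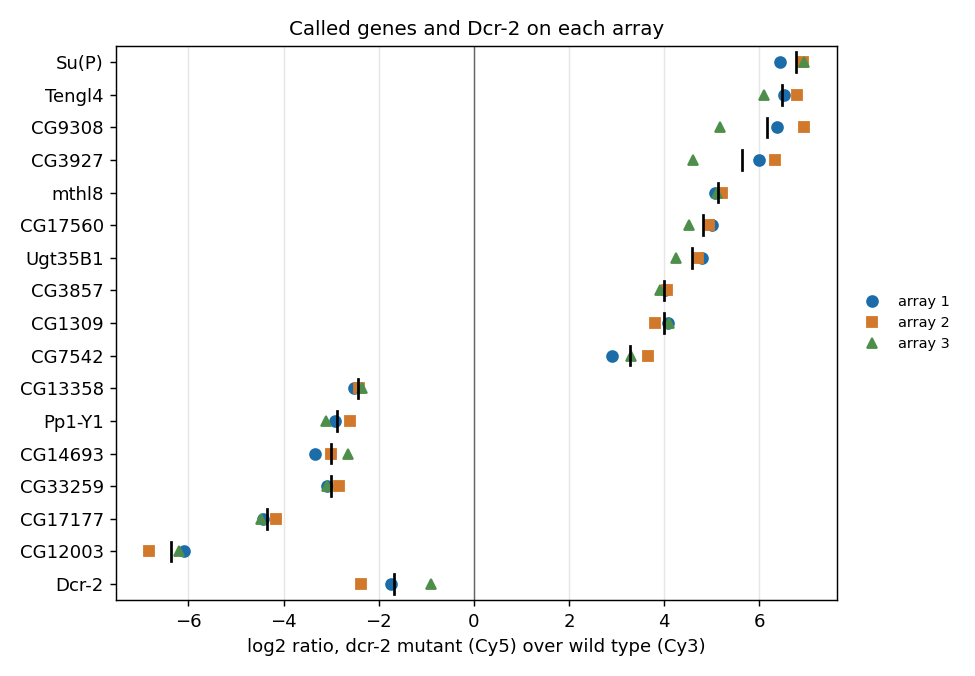
Log2 ratio of mutant over wild type for the 16 called genes and Dcr-2, with a point per array and a black bar at the mean of 3 arrays. The called genes kept their side of 0 on every array, from 6.77 for Su(P) to -6.37 for CG12003, and for CG9308, mthl8, Ugt35B1 and Pp1-Y1 the plotted ratio rests on a channel not well above background.

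The count of called genes depended on single replicates. It was 13 without replicate 1, 30 without replicate 2 and 280 without replicate 3, where 218 of the 280 were lower in the mutant. At an unadjusted p of 0.05 there were 1875 genes, against 638 given by chance. Across all tested genes 39.5% had the same direction on every array, where chance gives 25% if the arrays are independent. The ratios of arrays 1 and 2 correlated (Pearson r = 0.74), which alone raises this share. The excess is therefore no measure of agreement with array 3. A dye bias shared by the arrays would raise both counts as well.

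Each array carried 43603 gene spots, and between 83.3% and 86.1% of them were well above background in each channel. Median spot signals lay between 1576 and 2210 in the wild-type channels and between 1804 and 2556 in the mutant channels, against median local backgrounds of 43 to 56. No gene spot was saturated. The log ratios of arrays 1 and 2 correlated across genes (Pearson r = 0.74), those of arrays 1 and 3 less so (r = 0.20), and those of arrays 2 and 3 not in the same direction (r = -0.06). These correlations are across genes, which are not independent replicates.

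Dcr-2 itself (CG6493) was read as a check of the labels. Its probe on 2R (13462612 to 13462671, dm3 assembly) gave a ratio of -1.68 ± 0.74 (SD, n = 3) and was lower in the mutant on 3 of 3 arrays, at -1.74, -2.38 and -0.90. The adjusted p was 0.253 by limma, so Dcr-2 did not pass over all genes. Without replicate 3 its ratio was -2.06 with an adjusted p of 0.0377, without replicate 2 it was -1.32 (adjusted p = 0.388), and without replicate 1 it was -1.64 (adjusted p = 0.997). A further Dcr-2 probe gave -0.89 ± 0.70 (SD, n = 3), also lower on every array. Neither allele removes the gene, so these probes report transcript level alone.

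The siRNA pathway, on which the mutation acts, was examined as a list that includes Dcr-2 itself. None of its 21 tested members passed over all genes, and 0 passed adjusted over the list alone. The median of the list was -0.25 (camera adjusted p = 0.1 with the preset correlation, 0.939 with an estimated correlation). With the preset correlation and without replicate 3 the list passed, with a median of -0.28 (adjusted p = 0.0359), and without replicate 2 its median was -0.12 (adjusted p = 0.704). The Dicer-2 partner r2d2 had a ratio of -0.09 ± 0.34, the slicer AGO2 -0.05 ± 0.59 and loqs -0.13 ± 0.17 (SD, n = 3 each). The probes of loqs disagreed, the other one reading -0.63 ± 0.56. Rm62, an RNA helicase, had a ratio of 1.198 ± 0.43, Cbp80, of the nuclear cap-binding complex, -0.98 ± 0.55, and vig -0.70 ± 0.42, none past the threshold. With the mean of all its probes Rm62 was called, at 3.57 (adjusted p = 0.0166), so its probes differ.

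Long hairpin RNAs are known precursors of endogenous siRNAs, and mus308 (current symbol PolQ), a DNA polymerase gene, is a known target of such siRNAs. The 5 tested members of this list had a median of 0.38, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.229 with the preset correlation and 0.939 with an estimated correlation). Without replicate 2 the median was 0.21. PolQ was at 0.55 ± 0.42 and higher on 3 of 3 arrays, with an adjusted p of 0.384 by limma. Its other probe gave 0.35 ± 0.25. The hairpin RNA CR32207 was at 0.79 ± 0.39 (adjusted p = 0.296), CR32205 at 0.38 ± 0.31 and CR33940 at -0.24 ± 0.20 (SD, n = 3 each).

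Of the antiviral and JAK-STAT genes, 0 of 16 passed over all genes and 1 passed adjusted over the list alone. This was pst (pastrel), a gene known for restricting viruses, at -2.88 ± 0.39 (SD, n = 3) and lower on 3 of 3 arrays, with an adjusted p of 0.0508 over all genes and 0.00115 over the list alone. pst passed over all genes with the scanner's processed signals (adjusted p = 0.0359), with normexp offset 16 (0.0417) and with no background correction (0.0493), and the mean of all its probes gave -1.69 (0.147). Vago, an antiviral gene downstream of Dicer-2, was at -0.15 ± 0.78 with 2 arrays lower and 1 higher. The list median was -0.19 (camera adjusted p = 0.224 with the preset correlation, 0.939 with an estimated correlation). With the preset correlation the list passed without replicate 3 (median -0.59, adjusted p = 0.00317) and not without replicate 2 (-0.06, adjusted p = 0.783). The JAK-STAT ligand upd1 read -2.47, -3.01 and 0.30 on the 3 arrays. The kinase hop was at -0.57 ± 0.17 and et, a negative regulator of the pathway, at 0.54 ± 0.37.

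Stress and immune genes differed in direction between arrays. Turandot stress genes had medians of -1.88 and -1.67 on arrays 1 and 2 and 0.49 on array 3 (8 members, 0 past the threshold, camera adjusted p = 0.077). TotM read -3.06, -3.15 and -0.15, and TotC -2.13, -1.84 and 0.07. The 26 antimicrobial peptide genes had medians of -1.17, -1.04 and 1.52 on arrays 1, 2 and 3 and a median of -0.20 over all, while the camera test pointed up without passing (adjusted p = 0.763). Over all genes 0 of them passed, and 2 passed adjusted over the list alone, Drs (1.69 ± 0.39) and Drsl1 (1.502 ± 0.32), both encoding antifungal peptides of the drosomycin family and higher on 3 of 3 arrays. Heat shock and chaperone genes had medians of -0.19, -0.62 and 1.26 (24 members, adjusted p = 0.302, 0 calls). Among them l(2)efl, a small heat shock protein gene, was at 0.86 ± 0.49 and higher on 3 of 3 arrays. Hsp70Bb had values of -1.34 and -1.19 on arrays 1 and 2 and none on array 3. On array 3 Hsp70Ba was far higher in the mutant (16.6) than in the wild type (10.7), in single channels on the log2 intensity scale. The values of Hsp70Bb are therefore no sign of steadily lower Hsp70 genes. Without replicate 3, the Turandot, antimicrobial and heat shock lists passed as lower, with medians of -1.71, -1.21 and -0.32 and the preset correlation. With an estimated correlation over all 3 arrays, their adjusted p values were 0.939, 0.996 and 0.939. Turandot genes had a median of -0.67 without replicate 1 and -0.66 without replicate 2. Against random lists matched on intensity, the Turandot (adjusted p = 0.000978) and heat shock (adjusted p = 0.0497) lists passed. Those random lists draw genes independently, so these p values measure spread over genes and not over the 3 arrays, between which both list medians changed sign. With the preset correlation, without replicate 1 the antimicrobial and heat shock lists passed as higher, with medians of 0.13 (adjusted p = 0.0172) and 0.67 (adjusted p = 0.00227), and without replicate 2 the heat shock list did so with 0.74 (adjusted p = 0.00533).

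Of 44 gene lists tested, 9 passed camera with the preset inter-gene correlation, 7 higher and 2 lower in the mutant. With an estimated correlation 0 passed, each of the 9 having an adjusted p of 0.939, and 0 had an unadjusted p under 0.05 where the preset gave 21. That version of camera rests on 2 residual degrees of freedom. Its smallest unadjusted p over the 44 lists was 0.152, so not passing it says little against a list. The test fry, which asks whether the genes of a list move one way, passed 0 lists.

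Cytoplasmic ribosomal protein genes were higher in the mutant (median 0.50 over 88 genes, camera adjusted p = 1.8e-14, 0.939 with an estimated correlation). The median was above 0 on every array, at 0.33, 0.41 and 0.73, and 64 genes were higher on all 3 arrays against 3 lower. RpS25 was at 1.04 ± 0.27, RpL27 at 0.95 ± 0.12 and RpS9 at 1.03 ± 0.31 (SD, n = 3), and 0 genes of the list passed over all genes or adjusted over the list alone. Leaving out any replicate kept the list past the threshold with the preset correlation.

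Adult muscle genes were higher with a median of 1.22 (24 genes, camera adjusted p = 6.5e-08, 0.939 with an estimated correlation). Of these, 0 passed over all genes and 7 adjusted over the list alone. The myosin light chain genes Mlc1 and Mlc2 were at 2.44 ± 1.25 and 2.28 ± 1.44, the flight muscle actin gene Act88F at 1.54 ± 0.84 and wupA (troponin I) at 1.61 ± 0.94. Array 2 had by far the highest list median, 2.50, against 0.95 and 0.42 on arrays 1 and 3. Read as single channels, muscle genes of the wild-type RNA of replicate 2 lay 1.71 below their mean over the 6 channels, while the other wild-type RNAs lay at -0.25 and 0.11. This wild-type RNA also stood apart over all genes, at -78.9 on the first principal component (54.1% of the variance) against -17.1 to 41.2 for the other 5 channels. Without replicate 2 the median was 0.68 and the list still passed (adjusted p = 1.64e-07).

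Oxidative phosphorylation genes had a median of 0.39 (92 genes, camera adjusted p = 4.02e-07, 0.939 with an estimated correlation), with medians of 0.17, 1.15 and -0.06 on the 3 arrays. ATPsynbeta, a subunit of the ATP synthase, was at 2.18 ± 0.49 and was the 1 member past the threshold adjusted over the list alone, with 0 over all genes. Cyt-c1 was at 1.31 ± 0.29, ATPsynC at 1.70 ± 0.82 and blw at 1.27 ± 0.52. Without replicate 2 this list did not pass (median 0.01, adjusted p = 0.28). The wild-type RNA of replicate 2, which stood apart over all genes, lay 0.71 below the mean over channels for these genes.

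Phototransduction and eye genes had medians of 0.18, 1.46 and -0.26 on the 3 arrays and 0.36 over all (29 genes, 0 called, camera adjusted p = 0.013, 0.939 with an estimated correlation). The same wild-type RNA lay 1.07 below the mean over channels for eye genes, and without replicate 2 the median was -0.02 (adjusted p = 0.931). The opsin gene Rh3 read 0.92, 3.62 and 0.38, and norpA, the eye phospholipase C gene, was at -0.54 ± 0.20. Mitochondrial ribosomal protein genes had a median of 0.13 (74 genes, 0 called, adjusted p = 0.0145, 0.939 with an estimated correlation) and -0.03 without replicate 2 (adjusted p = 0.773), and it did not pass without replicate 3 either (0.14, adjusted p = 0.0503). Within it, mRpL38 was at 0.71 ± 0.10 and mRpS14 at 0.87 ± 0.50.

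Cuticle protein genes had a median of 0.42 (112 genes, camera adjusted p = 0.000209, 0.939 with an estimated correlation), with array medians of 0.00, 0.98 and 0.28, and 0.10 without replicate 2 (adjusted p = 0.046). The wild-type RNA of replicate 2, which stood apart over all genes, lay 0.60 below the mean over channels for these genes, and the other wild-type RNAs at -0.03 and 0.01. The 1 member past the threshold adjusted over the list alone went against the list. This was Cpr50Ca, at -3.75 ± 0.89 and an adjusted p of 0.0845 over all genes (0.0493 with the scanner's processed signals). TwdlD at -1.22 ± 0.18 and Cpr76Bc at -1.90 ± 1.06 were also below 0, and Ccp84Ac was at 1.09 ± 0.44. Odorant-binding protein genes had a median of 0.15 (47 genes, 0 called, adjusted p = 0.0269, 0.939 with an estimated correlation), with Obp57c at 1.95 ± 0.80 and Obp56d at 2.59 ± 1.30, and a median of 0.03 without replicate 2 (adjusted p = 0.189). Against random lists matched on intensity this list did not pass (adjusted p = 0.177).

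Of the 9 lists past the preset test, the miRNA pathway and the circadian clock were the 2 lower in the mutant. The 17 miRNA pathway genes had a median of -0.53 (camera adjusted p = 0.00231, 0.939 with an estimated correlation), and 10 were lower on all 3 arrays against 1 higher. Ranbp21, which exports miRNA precursors from the nucleus, was at -0.96 ± 0.28, Not1 at -0.80 ± 0.01 and DCP2 at -0.75 ± 0.32, with 0 called over all genes or adjusted over the list alone. Without replicate 2 the median was -0.33 (adjusted p = 0.053). The 11 circadian clock genes had a median of -0.31 (adjusted p = 0.0269, 0.939 with an estimated correlation), and 2 passed adjusted over the list alone, cwo (-1.03 ± 0.26) and dco (-0.86 ± 0.20). Without replicate 2 the clock list had a median of -0.44 and did not pass (adjusted p = 0.189), nor did it against random lists (adjusted p = 0.201), and vri read -3.76, -3.62 and 0.58.

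**Figure D2:**
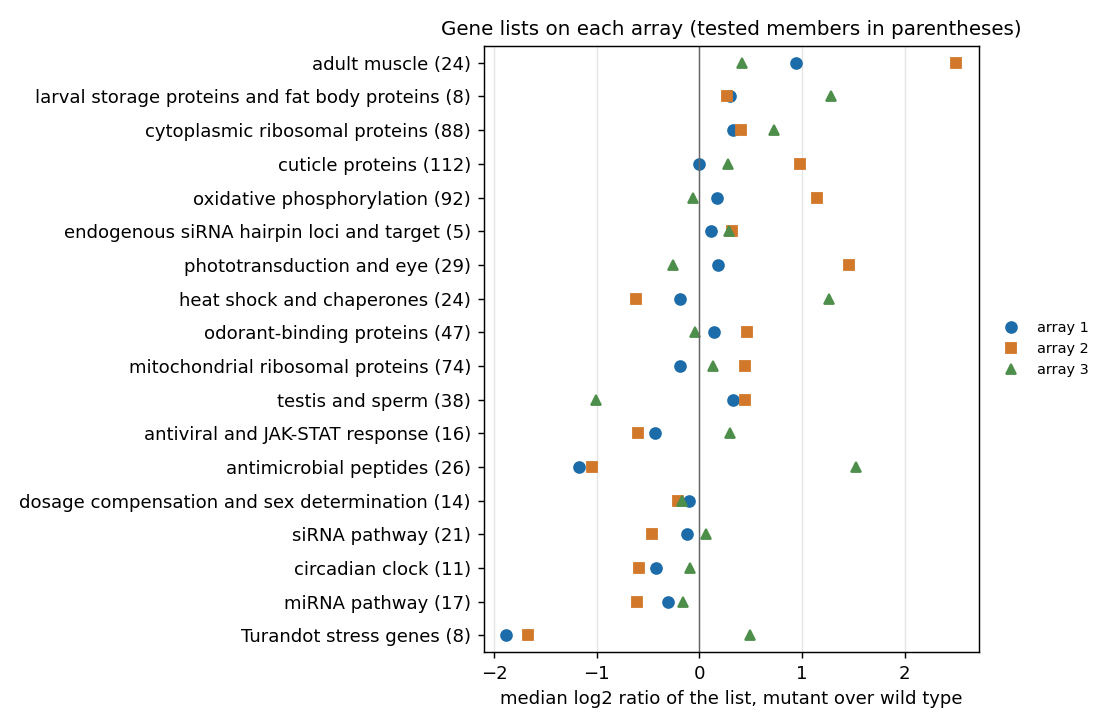
Median log2 ratio of each of 18 gene lists on each array, with the number of tested members in parentheses. Ribosomal protein genes lie above 0 on every array, muscle genes are highest on array 2 (2.50), and antimicrobial peptides lie at -1.17 and -1.04 on arrays 1 and 2 and at 1.52 on array 3.

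Markers of stage and sex were read because pools of pupae can differ in both. The 53 late stage markers (eye and muscle) minus the 21 early stage markers (salivary glue and larval storage) gave differences of medians of 0.91, 2.21 and -0.80 on arrays 1, 2 and 3. The parts of the early set differed in sign on arrays 1 and 2. Salivary glue genes had medians of -0.98, -0.43 and 0.40 on the 3 arrays, and larval storage and fat body genes 0.30, 0.27 and 1.29. The pooled early median is therefore not a single reading of stage. Larval storage and fat body genes had a median of 0.68 (8 genes, 0 over all genes and 3 adjusted over the list alone, camera adjusted p = 0.0678 with the preset correlation, 0.939 with an estimated correlation), with Lsp1gamma at 1.23 ± 0.36, Lsp2 at 1.05 ± 0.49 and Obp99b at 0.89 ± 0.21. With the preset correlation this list passed without replicate 1 (0.90, adjusted p = 0.00858) and without replicate 2 (0.81, adjusted p = 0.0196), and not without replicate 3 (0.26, adjusted p = 0.354). Testis and sperm genes had medians of 0.33 and 0.44 on arrays 1 and 2 and -1.01 on array 3 (38 genes, 0 called, camera adjusted p = 0.686 with the preset correlation, 0.996 with an estimated correlation). With the preset correlation the testis list passed as lower without replicate 1 (-0.27, adjusted p = 0.0306) or replicate 2 (-0.34, adjusted p = 0.00999), and as higher without replicate 3 (0.35, adjusted p = 0.000313). The male-specific roX1 and roX2 RNAs averaged 0.07, 0.12 and -1.01, and the female yolk protein genes had medians of -0.68, -0.73 and 0.61. The yolk protein genes were dim, at 6.71 to 9.11 in single channels on the log2 intensity scale. The list of dosage compensation and sex determination genes had a median of -0.21 (14 genes, 0 called, adjusted p = 0.272) and -0.09 without replicate 3, with Sxl at -0.75 ± 0.32 and msl-2 at -0.64 ± 0.26.

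**Figure D3:**
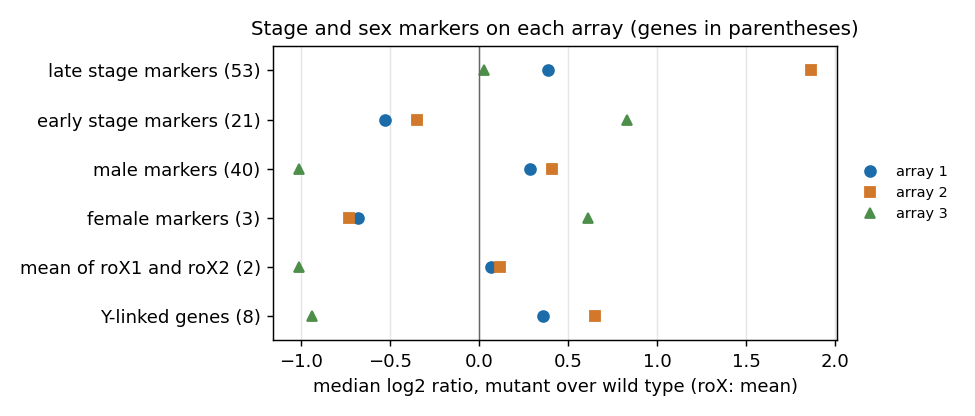
Median log2 ratio of stage and sex markers on each array (mean for roX1 and roX2). Late stage markers are highest on array 2 (1.87), and male markers, roX RNAs and Y-linked genes lie below 0 on array 3, where female markers lie above it (0.61).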

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

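The tests of array 2 and of the intensity bias of array 3 were chosen after the result was seen; the others were set beforehand, and Pp1-Y1 was left out of the Y-linked genes because its value had been seen.

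A pair of signals lie in data outside the comparisons. Control probes for an external RNA (E1A) read brighter in Cy5 than in Cy3 before dye normalization, with a median log2 ratio of 3.02 over 10 probes and 9 of them brighter on every array, where the median of the gene spots averaged 0.07 over arrays. Among 6618 probes with no gene name, 84 passed an adjusted p of 0.05 by limma, 39 higher and 45 lower in the mutant.

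The 16 called genes are the first pattern. With 3 arrays there are 4 assignments of the RNAs to the channels, too few for a share under 0.05, and the real one (1 of 4) gave 16 genes where the highest other gave 0. Stage markers differed by 0.66 and sex markers by 0.18 in the medians over arrays. Both differences changed sign on array 3, so the planned tests decided neither. Late minus early markers read 0.91, 2.21 and -0.80 on the arrays, and male minus female markers 0.97, 1.14 and -1.62. Within the early set, salivary glue and larval storage genes differed in sign on arrays 1 and 2, which weakens the stage reading. All 16 genes kept their direction, and the smallest ratio in size, of CG13358, read -2.52, -2.41 and -2.35. This argues against the stage or sex differences that these markers read as the cause of the 16 calls. The test calls only genes that are steady over the arrays, so their steadiness is no independent evidence. The argument holds for the 16 genes alone and not for stage or sex effects on other genes. A second probe existed for 3 of the genes, with a median of 2.73 in the called direction (SD 3.06), so a single-probe effect stays open for the other 13 and for CG9308, whose other probe read 0.50. The probes of Tengl4 lie close together (3R 6777297 to 6777356 and 6777374 to 6777433), so they are no independent check of a local effect. A second probe also cannot test dye bias. Genes on 2R were not over-represented (odds ratio 0.60, 95% interval 0.0659 to 2.66), an interval too wide to exclude background linked to the mutant chromosome. The loss of Dicer-2, dye bias and any difference in genetic background stay open together, as the design confounds them. Arms 3L and 3R are read under the other observations.

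The second pattern is that muscle, eye and oxidative phosphorylation genes are higher in the mutant on array 2 than on the others. Random lists matched on intensity argue against an intensity-dependent bias of that array left after loess. Loess had already taken out the trend with intensity, so the test could read only what remained. The smallest of the 3 lists' excesses was 1.16, and the central 95% of the lists matched to that group lay between -0.08 and 0.50. Genes are drawn independently in such lists, so they bear on intensity alone and not on other causes. The late stage markers are the muscle and eye genes themselves, so their low level in the wild-type RNA of replicate 2 shows which RNA departs but not why. Early stage markers, which are not in the pattern, lay 0.43 above the other wild-type RNAs there, yet the mutant RNA of replicate 3 had a higher level of them (0.34 against 0.29). An earlier stage of that wild-type pool and any other disturbance of this RNA, which stood apart over all genes, stay open, and no biological explanation was tested.

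The third pattern is that roX and testis genes are lower in the mutant on array 3 than on the others. Matched random lists argue against an intensity-dependent bias left after loess, as the shift was -1.47 and the central 95% of theirs lay between -0.39 and 0.33. The Y-linked genes were the planned test: 8 genes, all lower on array 3, had a median of -0.94 there against 0.36 and 0.65, a difference of -1.44. The pools of replicate 3 may therefore have held fewer males in the mutant than in the wild type, relative to the other replicates. In single channels both RNAs of replicate 3 departed, with testis genes at 0.69 in the wild type (others -0.20 and -0.33) and -0.35 in the mutant (others 0.07 and 0.14). The roX RNAs (-1.01 on array 3) are not testis genes, which argues against testis maturity as the cause of the whole pattern. Testis maturity stays open for the testis and Y-linked genes. Yolk genes read 0.61 but were dim, at 6.71 to 9.11 on the log2 intensity scale against 13.4 to 15.9 for the roX RNAs. They are weak support.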

How the results depend on the processing

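Counts and sizes depended on the processing, and no main call that stayed called turned. Ratios of genes with a dim channel moved most with the processed signals, as for CG33259 (-3.002 to -4.94) and CG3927 (5.64 to 7.28). The 16 genes called became 34 with the scanner's processed signals and 34 with the value table, 26 with normexp offset 16, 202 with median centring, 27 with an intensity trend and robust variance, and 75 with 6 unpaired channels. It became 9 with no filter and 8 with both channels above background, and the counts at least 2-fold were the same numbers under each. Under these and the other settings (14 in all), between 8 and 16 of the main calls stayed called, each in its direction. Of 13 named genes 8 stayed with loess and scale, 7 with no filter and 5 with both channels above background, where fewer of them were tested. The split was 160 higher and 42 lower with median centring and 10 and 3 with loess and scale, against 10 and 6; the cause was not tested. Leaving out 1 replicate gave 13 to 280 genes, changed at least 2-fold in each case, a share higher of 22.1% to 76.9%, a Dcr-2 ratio of -2.06 to -1.32, and 7 to 21 lists past the threshold. The 9 lists became 17 with median centring, 14 against random lists and 0 with an estimated correlation. The random lists draw genes independently, and the estimated correlation rests on 2 residual degrees of freedom, so neither count settles the matter. Testis and sperm genes turned to 0.51 with median centring, and over left-out replicates ranged from -0.34 to 0.35, antimicrobial peptides from -1.21 to 0.13 and heat shock genes from -0.32 to 0.74; the cause was not tested. Rm62 was called with the mean of all probes (3.57). The minimum-fold test gave no value for lists. The correction for probe base composition was not run. The fit on ratios within each array is itself paired, and the 6 unpaired channels are its alternative. Signal over background limits CG9308, mthl8, Ugt35B1 and Pp1-Y1 to bounds, and leaves the sizes of CG33259 and CG3927 uncertain.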

Other observations

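The probe with the highest ratio of the series had no gene name. The test on chromosome arms below and the items in this part were chosen after their values were seen. The highest unnamed probe, at 3R 1826574 to 1826631, was at 7.87 ± 0.18 (SD, n = 3, adjusted p = 0.0024 by limma) and lies 36 bases from the probe of Rm62 (1.198). An unnamed probe at 3R 998301 to 998360 was at 4.59 ± 0.11, 226 bases from a probe of cno that read 5.33, while the probe that represents cno read -1.95. An unnamed probe at X 697740 to 697799 was at -4.36 ± 0.74, 418 bases from the probe of the called gene CG13358 (-2.43).

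Called features lay on chromosome 3 more often than tested ones. Of 15 called genes on the main arms, 11 (73.3%) were on 3L or 3R, where 44.5% of tested genes lie (odds ratio 3.43, 95% interval 1.015 to 14.8, Fisher's exact p = 0.035, two-sided). Among probes with no gene, 44 of 70 called probes were on these arms (odds ratio 2.26, 95% interval 1.36 to 3.83, exact p = 0.000943), where 43.1% of tested probes lie. Genetic background outside the second chromosome, which carries the dcr-2 alleles, may contribute to the calls. Neighbouring probes on 1 transcript are not independent, so the interval for probes is too narrow.

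A few genes were lower on arrays 1 and 2 and far higher on array 3. Hsp70Ba read -1.90, -1.68 and 5.94, ImpL1 -2.47, -3.24 and 5.46, and Cht8 -2.42, -4.37 and 5.34 on arrays 1, 2 and 3. In single channels ImpL1 was highest in the mutant RNA of replicate 3 (16.3) and the wild-type RNA of replicate 2 (16.3) and lowest in the wild-type RNA of replicate 3 (10.9), on the log2 intensity scale.

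The digestive enzyme genes Jon25Bii (-1.503 ± 0.26) and Jon66Ci (1.53 ± 0.29) had ratios of opposite sign, each with 1 direction on 3 of 3 arrays (SD, n = 3). Each had an adjusted p of 0.153 over all genes and 0.0149 over its list alone.

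Pp1-Y1 differed from the other Y-linked genes on arrays 1 and 2. It was lower in the mutant on every array, while the 8 others, each averaged over arrays, had a median of 0.03, with medians of 0.36, 0.65 and -0.94 on the 3 arrays, the last in the same direction as Pp1-Y1.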
